A study of Mus musculus with 4 samples.

How the data were processed

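Droplet-based 5′ single-cell RNA libraries of γδ T cells from mouse spleen were analysed, 2 titled WT and 2 titled KI. Per the labels, splenocytes were enriched for T cells and sorted by flow cytometry after staining for B220, CD3, CD11c and the δ and β chains of the T cell receptor. The deposited matrices hold raw UMI counts per gene and cell barcode, made with Cell Ranger (version 3.1.0 per the file headers) and not normalized. The genome build and annotation are not stated, so no coordinates are given. The labels list several read configurations without saying which library had which, so a difference between sequencing runs was not tested. V(D)J reads, which the series description mentions, were not used here. Groups were taken from the titles, because the strain label is the same on all 4 libraries. The labels do not say whether KI mice carried 1 or 2 copies of the allele or whether WT mice were littermates. The labels state no pairing of the libraries, so the replicate number was not part of the design.

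The matrices held 19416 barcodes. Cells with fewer than 500 genes or with 10% or more mitochondrial UMIs were removed, which took 3.69%, 6.09%, 20.5% and 9.74% of the barcodes of WT replicates 1 and 2 and KI replicates 1 and 2 and left 17419 cells. The automatic threshold of Scrublet (in scanpy 1.11.5) called 26 doublets (0.149%), too few to be plausible, so the cells with the highest scores were removed in each library up to an expected 0.8% per 1000 cells, 675 in all. The 16744 retained cells had medians of 1322, 1298, 1414 and 1327.5 genes in the same order of libraries. Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes were chosen without the 660 T cell receptor and immunoglobulin segment genes, and cells were clustered by the Leiden method (leidenalg 0.10.2) on 20 principal components and 15 nearest neighbours at resolution 0.5, with random seed 1 and no integration of libraries. A cluster got a cell type name when at least 3 of its 10 leading genes were on that type's marker list and at least 3 markers were raised 1.5-fold at 10 CPM or more, with 20 CPM added for the folds. A tie with another list over the 10 leading genes gave no name, which left cluster 3 unnamed, with 4 natural killer cell and 4 type 1 cytotoxic markers among them (5 and 16 raised). Clusters whose median UMIs per cell were under 0.5 of the library median were called low-UMI clusters.

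UMIs were summed per library over all cells, and per library and cluster for clusters with at least 20 cells in every library. Sums were tested with edgeR 4.0.16 (TMM normalization, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05) under R 4.3.3. Receptor and immunoglobulin genes stayed in the tables but were counted apart. Numbers of cells per cluster, and of cells per γ V gene among cells with UMIs of a single γ V gene, were tested with the edgeR quasi-likelihood test against the library's number of cells. Differences between clusters in the effect of genotype were tested as an interaction in edgeR with library as block, cluster 0 against each other cluster. Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and fry beside it. The lists were naive or central memory, interleukin-17-producing γδ T, type 1 cytotoxic, γδ NKT, immature thymic emigrant, cycling, interferon response, B cell, αβ T cell, natural killer cell, myeloid, neutrophil, erythroid or platelet, T cell receptor response, inhibitory receptor, dissociation stress, T cell receptor signalling and sex-linked genes. A list with fewer than 3 measured members was not tested, which left out the neutrophil and the erythroid or platelet lists.

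The main comparisons, tests, lists and the rule for naming genes were chosen before the data were examined. Over all cells the text names the 15 genes with the largest positive and the 15 with the largest negative change among those past the threshold, with both KI libraries on the same side of both WT libraries, a mean logCPM of at least 3 and a symbol that is not a placeholder. Within clusters it names 8 in each direction, or, where fewer than 10 passed, the 10 with the smallest p. From each list it names the 4 members with the smallest p past the threshold, or the 3 most abundant if none passed, and it names every V gene with over 1% of its family's UMIs. Other genes were named after their values were seen.

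The methods were tested on simulated data with known changes. Over all cells 82.8% of genes changed 2-fold and 98.0% of genes changed 4-fold were recovered, and 7.69% of the calls were false. In cluster 1 these values were 85.6%, 97.9% and 5.41%, and in cluster 4, with few WT cells, 32.6%, 88.3% and 3.39%. For numbers of cells, 86.3% of the clusters set to rise 4-fold were recovered over 100 tables. The spread simulated between libraries was preset and smaller than some spreads in the data. Cluster 10 held 4.68% and 1.90% of cells in WT replicates 1 and 2, and cluster 8 held 8.53% and 2.59% in KI replicates 1 and 2. For clusters that vary like these the recovery was not measured.

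Alternatives were DESeq2 1.42.0 size factors and Wald test, no filter on low counts, the replicate number as a block, each library left out, doublets kept, stricter cell filters (1000 genes, 5% mitochondrial UMIs), cells thinned to 1500 UMIs with shallower cells left out, receptor and immunoglobulin genes removed from the tables or kept in the clustering, resolutions 0.3 and 1, genes centred within each library, TMM over clusters, 2 other ways to give a cell its γ V gene, every library reweighted to the same mixture of clusters (limma), and low-UMI clusters or cluster 3 left out. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 was used for the rest.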

Results

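The series measured the transcripts of single γδ T cells sorted from the spleens of mice 10 weeks old, with 2 libraries titled WT and 2 titled KI. The strain label, which is the same on all 4 libraries, names an allele of Tcrd, the locus of the T cell receptor δ chain, built from the segments V6, D2 and J1, so the titles alone separate the groups. The labels do not say whether KI mice carried 1 or 2 copies of that allele, or whether WT mice were littermates. The question, as the series title poses it, is what the functional subsets of a γδ T cell pool with a fixed δ chain look like. After quality filters 16744 cells remained, 3525 and 6322 in WT replicates 1 and 2 and 4231 and 2666 in KI replicates 1 and 2. These cells held 10880383 and 19719847 UMIs (counted RNA molecules) in the WT libraries and 14390022 and 8776343 in the KI libraries, with medians of 2862 and 2930 UMIs per WT cell and 3280 and 3136.5 per KI cell. The labels do not say that the libraries came from separate mice, so every p-value measures only the spread between these libraries. With 2 libraries against 2, a two-sided exact permutation test cannot go below p = 0.333, and adjusted p-values come from edgeR models that share information over genes, clusters or V genes. Principal components were taken over the 5635 more abundant genes outside the receptor and immunoglobulin loci. On the first, which held 63.5% of the variance between the library sums, both WT libraries had negative scores (-9.39 and -6.50). Both KI libraries had positive ones (6.84 and 9.05). The second held 25.2% and separated the replicate numbers. Replicate 1 scored 5.68 in WT and 3.68 in KI, and replicate 2 scored -7.26 in WT and -2.10 in KI.

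Transcripts of the δ chain V genes differed between the groups, and Trav13-4-dv7 was nearly absent from KI. V genes of the Vδ6 family, the segment that the strain label names, supplied 20.7% ± 0.302 (SD, n = 2) of the δ V gene UMIs in WT and 76.4% ± 2.51 (SD, n = 2) in KI. Trav13-4-dv7 dropped from 26.8% ± 2.92 to 0.131% ± 0.0177, Trdv1 from 11.1% ± 0.104 to 2.22% ± 0.244 and Trdv5 from 18.0% ± 0.971 to 2.24% ± 0.376 (SD, n = 2 each). Trdv2-2 stayed abundant among the δ V transcripts of KI cells, with 14.7% ± 2.68 of these UMIs against 17.5% ± 1.28 in WT (SD, n = 2). Cells with at least 1 UMI of the Vδ6 family made up 31.4% of WT and 69.9% of KI cells, or 24.6% and 49.0% with every cell thinned to the same number of UMIs. Cells with a UMI of any other δ V gene made up 75.3% of WT and 23.5% of KI cells, or 69.4% and 15.6% after thinning. The libraries held no second cell type in which δ V genes should be silent, so the level that free RNA gives was not measured on such cells. Trav13-4-dv7 was seen in 0.249% of KI cells.

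As fold changes over all cells, Trav13-4-dv7 fell by 9.17 on the log2 scale (SE 0.16, adjusted p = 1.75e-09), Trdv5 by a log2 change of -4.49, Trdv1 by -3.80 and Trdv2-2 by -1.72. The rarer genes Trav21-dv12 (-3.78) and Trdv4 (-3.05) fell too, while Trav14d-3-dv8 (-0.47, adjusted p = 0.255) and Trav16d-dv11 (-0.22, adjusted p = 0.614) did not pass. Within the Vδ6 family Trav15-1-dv6-1 rose by a log2 change of 1.83 (SE 0.13, adjusted p = 4.98e-05), while Trav15-2-dv6-2 and Trav15d-1-dv6d-1 had log2 changes of -1.49 and -4.31. These near-identical copies are uncertain as single genes, and the family total is the safer measure. The δ V transcripts were fewer in KI cells, 679 ± 49.3 CPM against 1875 ± 78.1 in WT (SD, n = 2), although those of the Vδ6 family were more, 519 ± 54.7 against 389 ± 21.9. Trdc, the constant region of the δ chain, had 436 ± 8.33 CPM in KI and 480 ± 0.485 in WT, a log2 change of -0.13 that did not pass the test (adjusted p = 0.468). Trac, the constant region of the α chain, rose (log2 change 0.47, adjusted p = 0.00596), as did the γ constant genes Tcrg-C1 (0.36, adjusted p = 0.0386) and Tcrg-C4 (0.36, adjusted p = 0.0448). Tcrg-C2 had a log2 change of 0.27 (adjusted p = 0.0715), Trbc1 of 0.18 (adjusted p = 0.392) and Trbc2 of 0.23 (adjusted p = 0.561). In all, 25 receptor and immunoglobulin segment genes changed, 7 upward and 18 downward.

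**Figure D1:**
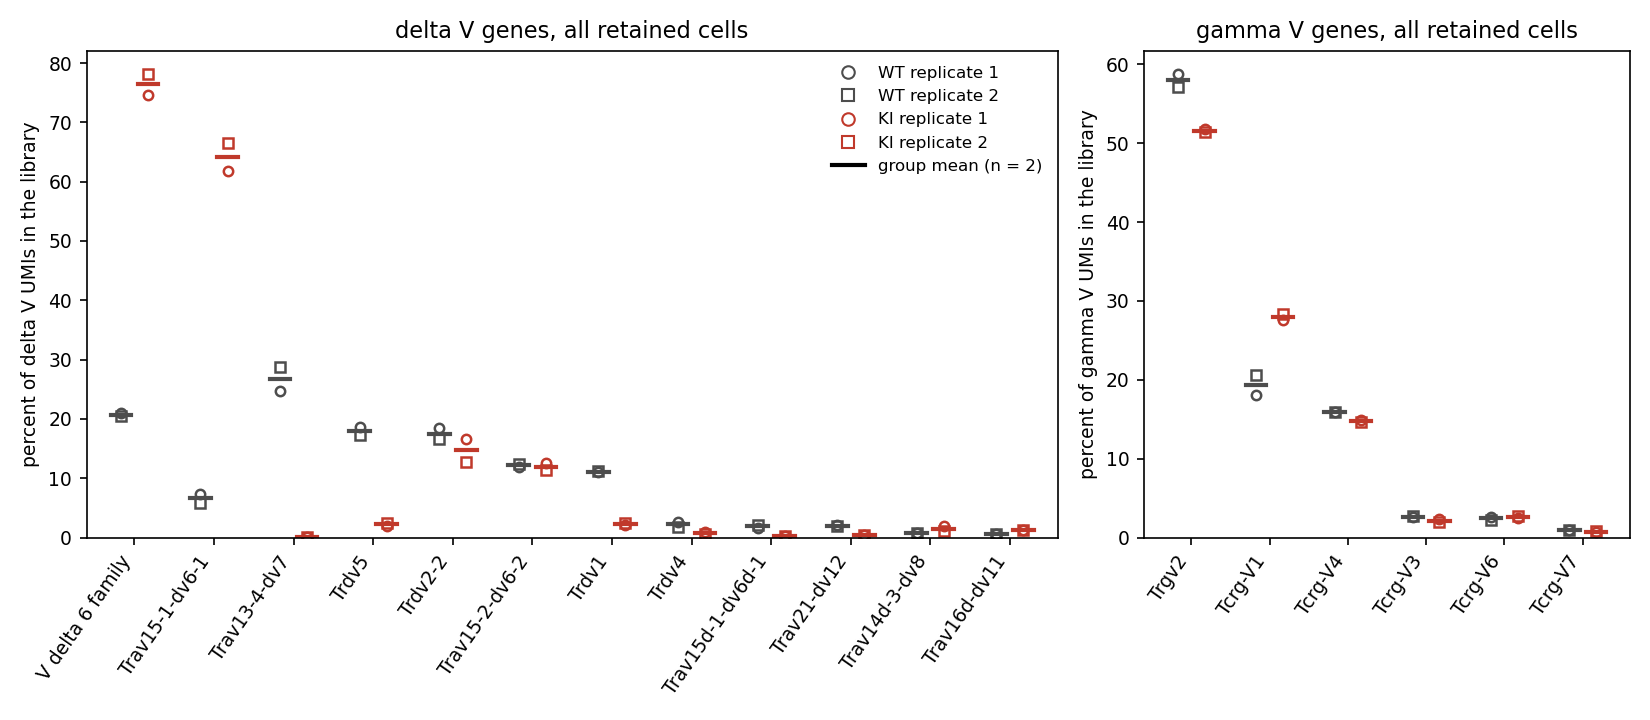
Percent of δ V gene UMIs (left) and of γ V gene UMIs (right) held by each V gene in the retained cells of each library; circles and squares are replicates 1 and 2, grey WT and red KI, and bars are group means (n = 2). The Vδ6 family stands at 20.7% in WT and 76.4% in KI, Trav13-4-dv7 at 26.8% and 0.131%, and Tcrg-V1 at 19.3% and 28.0%.

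V genes of the γ chain shifted less than those of the δ chain. Tcrg-V1 supplied 19.3% ± 1.73 of the γ V gene UMIs in WT and 28.0% ± 0.603 in KI, and Trgv2 58.0% ± 1.17 and 51.6% ± 0.297 (SD, n = 2). Tcrg-V4 had 15.9% and 14.8%, Tcrg-V6 2.43% and 2.60%, Tcrg-V3 2.65% and 2.14%, and Tcrg-V7 0.983% and 0.747%. UMIs of 2 or more γ V genes were found in 53.7% of cells, so the test used the 34.4% of cells with a single γ V gene. Among these, Tcrg-V1 cells rose from 15.3% ± 2.73 to 23.9% ± 0.135 (SD, n = 2; log2 change 0.60, SE 0.14, adjusted p = 0.0260). Also among these, cells with Tcrg-V3 rose from 1.86% to 3.39% (log2 change 0.85, adjusted p = 0.0129) and those with Tcrg-V6 from 1.42% to 2.80% (0.97, adjusted p = 0.0369). Trgv2 cells among them fell from 65.3% to 54.1% (log2 change -0.26, adjusted p = 0.0129), and Tcrg-V4 (15.2% and 15.0%), Tcrg-V5 (0.255% and 0.0794%) and Tcrg-V7 (0.655% and 0.748%) did not pass the test. Cells with a single γ V gene were 37.2% and 36.9% of WT and 29.8% and 31.9% of KI cells, and over all cells, where no test was made, a Trgv2 UMI was found in 70.6% of WT and 71.2% of KI cells (53.4% and 53.3% after thinning) and a Tcrg-V3 UMI in 4.499% and 4.44% (3.01% and 2.99%). A Tcrg-V1 UMI was found in 36.1% and 51.3% of cells (23.4% and 35.2%) and a Tcrg-V6 UMI in 1.98% and 3.85% (1.47% and 3.03%). Without either KI library, 0 of the 7 γ V genes passed. The call on Tcrg-V6 was also lost without WT replicate 2 (log2 change 0.75, adjusted p = 0.143) and with at least 2 UMIs required (0.55, adjusted p = 0.120) or a replicate block (1.00, adjusted p = 0.102), and that on Tcrg-V3 when each cell was given to the γ V gene with most UMIs (0.33, adjusted p = 0.0885).

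The γ V genes were also tested within clusters, which are described next. In cluster 0, Tcrg-V4 rose from 11.5% ± 0.0149 to 21.3% ± 3.42 of cells with a single γ V gene (SD, n = 2; adjusted p = 0.0167). In cluster 1, Tcrg-V4 fell from 22.1% to 12.7%, while Tcrg-V1 rose from 13.5% to 24.2%, Tcrg-V3 from 1.96% to 5.62% and Tcrg-V6 from 0.396% to 3.82% (adjusted p = 0.00840 for each). In cluster 3, Tcrg-V4 fell from 23.2% to 8.80% (adjusted p = 0.0217) and Tcrg-V6 rose from 0.629% to 8.40% (adjusted p = 0.0163). Whether these effects differed between clusters was not tested.

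Clustering without receptor and immunoglobulin genes gave 13 clusters, and 2 of them, of which cluster 4 carried the γδ NKT markers, were far larger in KI. Cluster 4, with Zbtb16 (PLZF, the transcription factor of innate-like T cells), Lmo4, Cd40lg, Ccr4, Icos and Il4, rose 15.6-fold, from 1.12% ± 0.220 of WT cells to 17.5% ± 3.22 of KI cells (SD, n = 2; log2 change 3.97, SE 0.32, adjusted p = 0.00232). Cluster 6, led by Ckb, Asb2, Cxcr6 (a chemokine receptor of tissue-homing T cells) and Id2, and with Zbtb16 at 129.7 CPM, Il4 at 97.1 CPM, Ifng at 64.9 CPM and Tbx21 at 232 CPM, rose 9.30-fold, from 1.09% ± 0.179 to 10.2% ± 4.23 (log2 change 3.21, SE 0.42, adjusted p = 0.00868). Both together held 2.21% ± 0.0412 of WT and 27.6% ± 1.00 of KI cells (SD, n = 2). Cluster 10, which carried genes of interleukin-17-producing γδ T cells such as Blk, Cd163l1 and Ccr6, fell from 3.29% ± 1.97 to 0.404% ± 0.171, 8.13-fold lower (log2 change -3.05, SE 0.65, adjusted p = 0.0263). Its WT libraries differed, at 4.68% and 1.90%, and the share of cluster 10 had a log2 change of -2.26 (adjusted p = 0.101) without WT replicate 1. Cluster 2, led by the T cell receptor response genes Nr4a1, Egr1 and Egr2 together with Myb, Tnfrsf9 and Sox4, fell from 13.02% ± 3.33 to 3.80% ± 0.0119 (log2 change -1.78, adjusted p = 0.0129).

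Cluster 0, with the CD8β gene Cd8b1, the gut-homing receptor gene Ccr9, Itgae, Dapl1 and Ccr7, fell from 32.7% ± 1.22 to 17.1% ± 0.721 (log2 change -0.94, adjusted p = 0.0263). Cluster 3, with the natural killer cell genes Fcer1g, Tyrobp, Ncr1 and Klrb1c, rose from 6.05% ± 0.455 to 12.1% ± 2.36 (log2 change 1.00, adjusted p = 0.0358). Cluster 9, made of cells with interferon response genes such as Ifit3, Ifit1 and Isg15, fell from 3.36% ± 0.989 to 1.51% ± 0.0686 (log2 change -1.14, adjusted p = 0.0375). Cluster 1, led by Ccl5 and Ly6c2, held 26.6% of WT and 20.1% of KI cells (adjusted p = 0.255), and cluster 5, led by Prdm16 and Cd7, 5.80% and 7.32% (adjusted p = 0.241). Cluster 11, with the cytotoxicity genes Gzma and Gzmb and with S1pr5 and Klrg1, held 0.882% and 0.2502% (adjusted p = 0.135), and cluster 12, with the cell cycle genes Mki67 and Top2a, 0.251% and 0.356% (adjusted p = 0.416). Clusters 7 and 8 had few UMIs per cell (medians of 1126 and 964) and no cell type name, and held 4.23% and 3.92% (adjusted p = 0.690) and 1.60% and 5.56% of cells (adjusted p = 0.0772), the latter with 8.53% in KI replicate 1 and 2.59% in KI replicate 2. Cells of cluster 8 had a median of 7.66% mitochondrial UMIs, against 2.02% to 3.23% in the other clusters, and Malat1 at 23707 CPM, against 3539 CPM in the rest. In all clusters except 7 and 12 the shares of the WT libraries did not overlap with those of the KI libraries, for which the exact permutation p is 0.333.

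**Figure D2:**
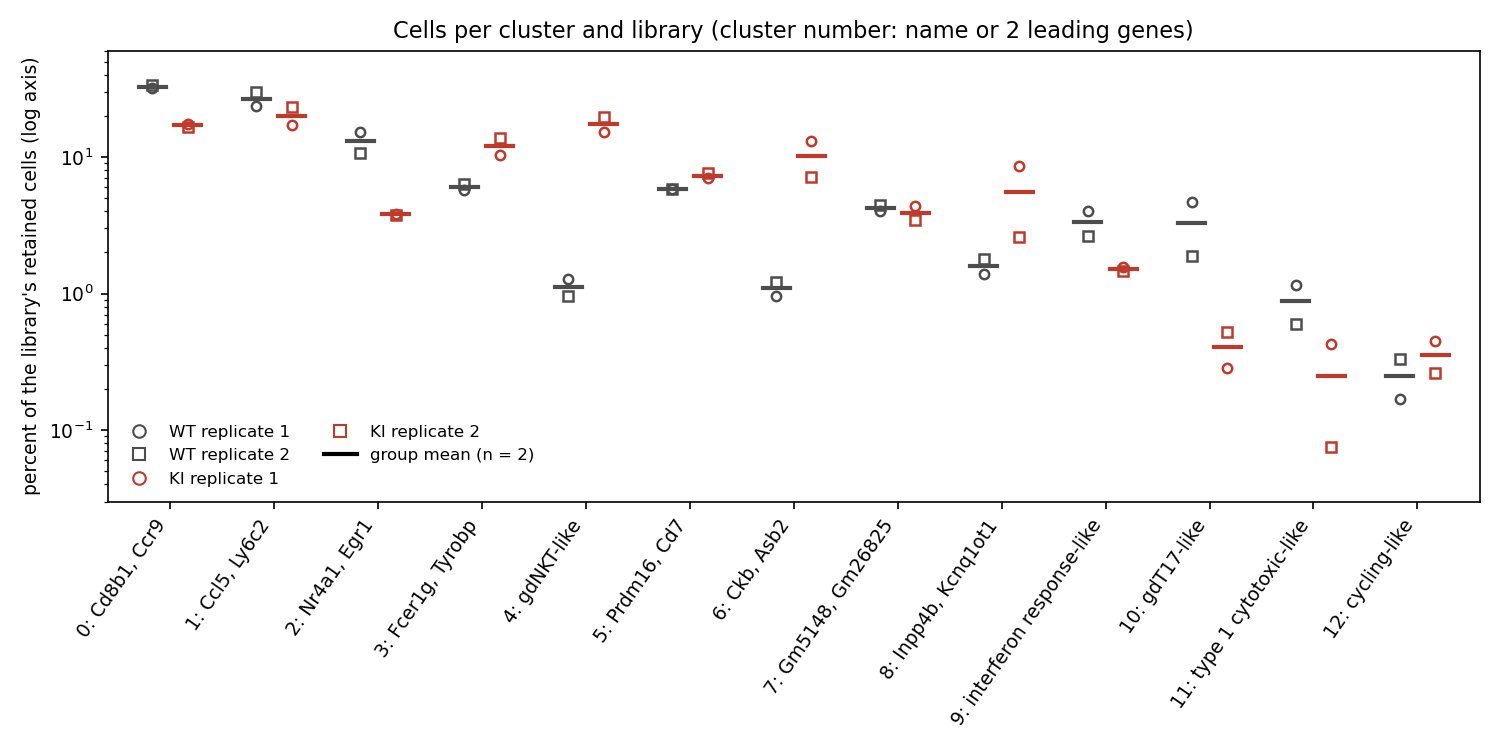
Percent of each library's retained cells (log axis) in each of the 13 clusters; circles and squares are replicates 1 and 2, grey WT and red KI, and bars are group means (n = 2). Cluster 4 stands at 1.12% in WT and 17.5% in KI, cluster 6 at 1.09% and 10.2%, and cluster 10 at 3.29% and 0.404%.

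Of the 13 clusters, 7 passed the threshold with all libraries, 0 without WT replicate 1 or without WT replicate 2, 2 without KI replicate 1 (clusters 4 and 6) and 3 without KI replicate 2 (clusters 4, 6 and 8), and without a WT library the share of cluster 4 had adjusted p = 0.0854 (without WT replicate 1) or adjusted p = 0.0516 (without WT replicate 2). The calls on cluster 0 (adjusted p = 0.0542), cluster 3 (0.106) and cluster 9 (0.0623) were lost with all cells thinned to the same number of UMIs. With a replicate block the share of cluster 0 had adjusted p = 0.117, the share of cluster 3 adjusted p = 0.115 and the share of cluster 9 adjusted p = 0.0971, and with TMM over clusters clusters 0 and 9 had 0.101 and 0.0903. With receptor genes kept in the clustering both had adjusted p = 0.0519, the share of cluster 9 also missed the threshold with doublets kept (0.0544) and with genes centred within libraries (0.0778), and cluster 3 did so at the higher resolution (0.0517). In 3 of the other clusterings cluster 3 joined cluster 1 (at least 95.5% of its cells). The joint cluster held 32.8% and 39.9% of WT and 31.0% and 40.5% of KI cells at the lower resolution. It held 22.6% and 29.7% against 21.3% and 28.2% with receptor genes kept. With genes centred within libraries it held 29.6% and 34.4% against 40.5% and 45.1%. It did not pass in any of them.

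Summed over all cells, 435 genes outside the receptor and immunoglobulin loci changed among 11278 tested genes of any kind, 269 upward and 166 downward. Cd40lg, which encodes the CD40 ligand of helper T cells, rose from 7.64 ± 0.292 to 96.0 ± 1.67 CPM (SD, n = 2; log2 change 3.64, SE 0.09, adjusted p = 3.97e-08), Il4, a type 2 cytokine gene, from 2.43 ± 0.493 to 28.4 ± 1.27 CPM (3.59, SE 0.17, adjusted p = 2.51e-06) and Zbtb16 from 13.2 ± 3.28 to 99.7 ± 4.01 CPM (2.96, SE 0.14, adjusted p = 2.22e-06). The transcription factor genes Zbtb7b (ThPOK), Lmo4 and Id2 rose by log2 changes of 2.48, 2.46 and 1.72, and the chemokine receptor gene Ccr4 by 2.76. The others of the 15 largest increases were Cap2 (2.68), Atp8a2 (2.53), Bcl2a1d (2.45), the Ly49 receptor gene Klra1 (2.41), Asb2 (2.14), Nebl (1.79), Qpct (1.76) and Ckb (1.76). Blk, a Src-family kinase gene used by interleukin-17-producing γδ T cells, had the largest decrease of the 15 named, from 21.6 ± 11.98 to 0.855 ± 0.712 CPM (SD, n = 2; log2 change -4.41, SE 0.52, adjusted p = 0.00127). Serpinb1a (-1.98) and the WC1-family gene Cd163l1 (-1.25), both high in cluster 10, fell as well. The transcription factor genes Myb (-1.38) and Eomes (-1.13), the B cell coactivator gene Pou2af1 (-1.67) and Cd8b1 (-1.01) fell, as did S1pr5, a receptor for egress into blood (-1.28), Plek (-1.29), Rln3 (-1.27), Actn2 (-1.14), Ms4a4c (-1.04), Ift80 (-1.03), Prss12 (-1.02) and Fam169b (-0.999). All 30 of these genes had both KI libraries on the same side of both WT libraries.

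**Figure D3:**
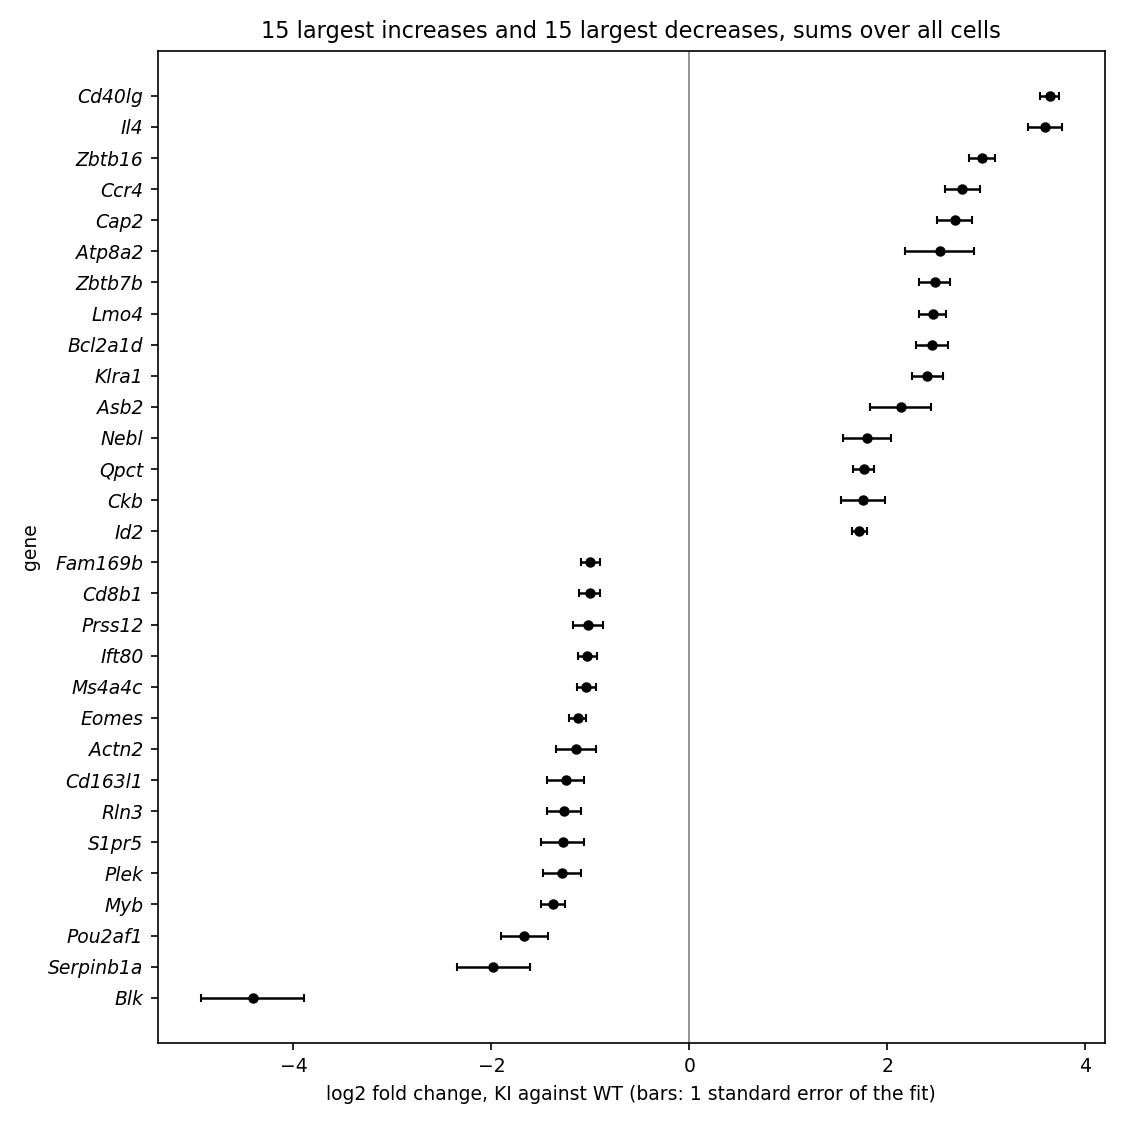
Log2 fold change of KI against WT, fitted on UMIs summed over all cells of each library (n = 2 per group), for the 15 largest increases and 15 largest decreases; points are fitted values and bars 1 standard error. Cd40lg stands at 3.64 and Il4 at 3.59, and Blk at -4.41.

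The number of changed genes was 75 without KI replicate 1, 154 without KI replicate 2 and 755 without WT replicate 2, 895 without a filter on low counts and 325 with the DESeq2 Wald test. With every library given the same mixture of clusters, 10 genes passed the limma test against 383 in the same test on cells as they fell. Of the 435 genes, 388 then kept their direction, with a median of 0.270 of the main log2 change, and Asb2 had a log2 change of -0.31. Profiles of small clusters, such as cluster 10 with 0.284% and 0.525% of KI cells, rested on few cells. The noise that this added to the equal mixture was not measured.

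Gene lists fixed before the data were examined were tested against all other genes with camera at a preset correlation, and 8 of the 16 measured lists passed; with an estimated correlation 0 did. The γδ NKT list rose, with 8 of 14 measured genes higher and 0 lower (8 and 0 adjusted over the list alone; adjusted p = 2.09e-12, and adjusted p = 0.226 with an estimated correlation). Besides Cd40lg, Zbtb16 and Il4, Cd4 rose from 0.580 to 5.97 CPM (log2 change 3.31), Icos by 1.52 and Izumo1r by 1.29. The natural killer cell list rose, with 4 of 6 genes higher (5 adjusted over the list alone; adjusted p = 7.14e-08, and adjusted p = 0.226 with an estimated correlation), namely Klrb1c (1.19), Fcer1g (1.29), Tyrobp (1.05) and Ncr1 (1.46). The cycling list rose, with 4 of 14 genes higher (11 adjusted over the list alone; adjusted p = 5.95e-09, and adjusted p = 0.335 with an estimated correlation), namely Pclaf (1.16), Top2a (0.97), Ccnb2 (1.57) and the chromatin gene Hmgb2 (0.42). The type 1 cytotoxic list did not pass (adjusted p = 0.248), with 6 of 23 genes higher and 2 lower (9 and 6 adjusted over the list alone): Id2, the NKG2D gene Klrk1 (1.03) and Ifng (1.03) rose and Eomes and the perforin gene Prf1 (-0.42) fell, and the list's median and mean were negative (-0.04 and -0.05) while camera gave it as up.

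Over all cells the list for interleukin-17-producing γδ T cells fell (adjusted p = 0.00171, and adjusted p = 0.641 with an estimated correlation), with 9 of 20 genes lower and 5 higher (13 and 5 adjusted over the list alone). Its lineage genes Blk, Sox13 (-3.01) and Kcnk1 (-5.84) fell, and the chemokine receptor genes Cxcr6 (0.99) and Ccr2 (1.70) and the nuclear receptor gene Rora (1.52) rose. Within clusters 1, 3, 5, 8 and 9 the same list rose by camera (adjusted p = 2.6e-05, 5.22e-06, 4.95e-09, 0.00029 and 0.00022). With an estimated correlation it passed in none of them (adjusted p = 0.187 to 0.476). It did not pass in clusters 0, 2, 4 and 6, and cluster 10 had too few KI cells for a test within it. Over all cells the naive or central memory list fell (adjusted p = 0.00185, and adjusted p = 0.433 with an estimated correlation), with 6 of 12 genes lower and 2 higher (7 and 2 adjusted over the list alone). Tcf7 (-0.58) and S1pr1 (-0.51) fell, and Igfbp4 (1.06) and Ly6c1 (1.15) rose. The immature thymic emigrant list fell, with Sox4 (-0.89), Ccr9 (-0.64) and Itm2a (-0.41) lower among 8 genes and 0 higher (5 and 0 adjusted over the list alone; adjusted p = 2.18e-05, and adjusted p = 0.284 with an estimated correlation). The interferon response list fell, with 3 of 18 genes lower (4 adjusted over the list alone; adjusted p = 0.00145, and adjusted p = 0.284 with an estimated correlation), namely Usp18 (-0.62), Ifit3 (-0.64) and Bst2 (-0.30). The T cell receptor response list fell, with 5 of 15 genes lower and 1 higher (8 and 2 adjusted over the list alone; adjusted p = 0.00222, and adjusted p = 0.284 with an estimated correlation). Id3 (-0.66), Nr4a1 (-0.59), Egr2 (-0.92) and Egr1 (-0.47) fell and Nfkbid (0.39) rose. With the same mixture of clusters in every library, the log2 changes of Nr4a1, Egr2 and Egr1 turned to 0.45, 0.46 and 0.43, that of Ifit3 to 0.043 and that of Igfbp4 to -0.041. None of them passed. By fry, which asks whether a list's genes move on balance in a single direction and compares them with no other genes, 2 lists passed, γδ NKT (adjusted p = 0.00325) and T cell receptor response (adjusted p = 0.0185).

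In the inhibitory receptor list (adjusted p = 0.980) Btla (0.74), Cd160 (0.61) and Entpd1 (1.67, and -0.076 with the same mixture of clusters) rose and Tigit (-1.83) fell among 9 genes (3 up and 2 down adjusted over the list alone), and the list's median was -0.05 while fry gave it as up. In the T cell receptor signalling list (adjusted p = 0.901) Cd247, the ζ chain gene, fell (-0.41) among 15 genes (2 up and 4 down adjusted over the list alone), with a median of 0.04 and a mean of -0.01. Of 12 dissociation stress genes 0 changed (0 adjusted over the list alone; adjusted p = 0.192), with Dnaja1 at 340 and 417 CPM, Junb at 279 and 351 CPM and Hsp90aa1 at 226 CPM in each group. Of 4 sex-linked genes 0 changed (1 up adjusted over the list alone; adjusted p = 0.486), and the Y-linked genes Eif2s3y, Ddx3y and Kdm5d were expressed in all 4 libraries.

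Besides the natural killer cell list, lists for other cell types did not pass over all cells. Among 9 B cell genes Cd79b fell (-0.46, adjusted p = 0.0227, and 0.15 with the same mixture of clusters), with 43.1 and 31.5 CPM, and 0 rose (2 down and 0 up adjusted over the list alone; adjusted p = 0.486 for the list). Among the αβ T cell genes Cd4 and Trac rose and Cd8b1 and Cd8a (-0.75) fell (2 and 2 adjusted over the list alone; adjusted p = 0.486 for the list). Among 4 measured myeloid genes Ctss fell (-0.32) and Cst3, Fcgr3 and Itgax had log2 changes of 0.02, 0.59 and -0.25 (1 down adjusted over the list alone; adjusted p = 0.486 for the list, with a mean of 0.01 and a median of -0.12). Neutrophil and erythroid or platelet genes were below the filter on low counts. Within cluster 1 the αβ T cell list rose by camera (adjusted p = 1.57e-09, and adjusted p = 0.312 with an estimated correlation) and by fry (adjusted p = 0.0071). Of its 5 measured genes 4 were higher, adjusted over the list alone. It also rose by camera in clusters 2 (adjusted p = 0.0330) and 5 (adjusted p = 0.00401). In clusters 0, 3, 4, 6, 7 and 9 it did not pass.

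Within clusters, the question is whether cells of the same kind differ between the groups. Outside the receptor and immunoglobulin loci, which all counts of changed genes within clusters leave out, the 10 clusters with enough cells gave 248 changes. These fell on 187 genes, of which 34 changed in at least 2 clusters and 15 in at least 3. Fcer1g and Klrk1 rose in 6 clusters each, Cd40lg in 5, Id2 and Zbtb16 in 4, and Ctla2a fell in 4. Of the genes that rose, Fcer1g and Klrk1 were leading genes of cluster 3, Cd40lg and Id2 of clusters 4 and 6, and Zbtb16 of cluster 4. These clusters were larger in KI. Whether free RNA or misplaced cells from them raised these genes in other clusters was not tested. Ctla2a, a leading gene of clusters 1 and 3, went the other way. Of the 435 genes changed over all cells, 82 changed in the same direction in at least 1 cluster and 350 passed in 0 clusters. The total was 133 without KI replicate 2, 474 without WT replicate 1, 626 without WT replicate 2 and 102 with the DESeq2 Wald test.

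In cluster 0, 52 genes changed, 47 upward and 5 downward. Genes of ribosomal proteins, counted after their values were seen, were 33 of the 47, with log2 changes of 0.30 to 0.46. Klrd1 (CD94) rose from 176 ± 0.390 to 367 ± 57.8 CPM (SD, n = 2; log2 change 1.05, adjusted p = 0.000104), Cd163l1 by 1.24, Dapl1 by 0.80, the chemokine receptor gene Cxcr3 by 0.72 and the chemokine gene Ccl5 by 0.50, and Gng2 (1.04), Traf5 (0.80) and Ppic (0.65) rose as well. Ccr9 (-0.62), Ift80 (-0.57) and S100a6 (-0.53) fell, Trac rose by 1.10 (adjusted p = 1.72e-05), and 4 genes of the type 1 cytotoxic list rose (6 adjusted over the list alone). The count was 113 without KI replicate 1, 24 without KI replicate 2 and 0 without either WT library.

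In cluster 1, 12 genes changed. Fcer1g rose from 38.8 ± 0.903 to 92.6 ± 30.7 CPM (SD, n = 2; log2 change 1.22, adjusted p = 0.0210), Ramp1 by 1.03, Cd8b1 by 0.89, Cd163l1 by 0.86, the stem cell antigen gene Ly6a by 0.82, Klrk1 by 0.82 and Cxcr6 by 0.65, and Ctla2a fell (-0.70). Egr1 (-1.29, adjusted p = 0.0570) and Bcl2 (-0.44, adjusted p = 0.0720) did not pass. The count was 3 without KI replicate 1 or KI replicate 2, 90 without WT replicate 1 and 155 without WT replicate 2.

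In cluster 2, 51 genes changed, and receptor response genes were higher in the KI cells placed in it, although the cluster was smaller. Nr4a1 rose by a log2 change of 0.80 (SE 0.13, adjusted p = 0.00163), Egr1 by 0.75, Tnfrsf9 by 0.79 and Irf4 by 2.46, 5 of the list's 14 measured genes being higher (11 adjusted over the list alone; adjusted p = 3.68e-11, and adjusted p = 0.218 with an estimated correlation). Nr4a1 had an effect in cluster 2 that differed from that in cluster 0 by 1.48 (adjusted p = 1.01e-06), and Egr1 by 1.35 (adjusted p = 1.07e-05). Nr4a1, Egr1 and Tnfrsf9 were also leading genes of cluster 2. If cells are placed in it by such genes, a shifted border could raise them here and lower them in cluster 0. The list test and the comparison with cluster 0 cannot tell this apart from higher expression per cell. Prdm16 rose by 2.69. Gpr183 (-1.01), Slc9a9 (-1.01), the chemokine receptor gene Cxcr4 (-1.20), Pde2a (-1.33), Orai2 (-1.23), Ahnak (-1.23) and Ctla2a (-0.90) fell. The antigen presentation and B cell genes Fcmr (4.25), H2-Eb1 (3.61), Cd79a (3.40), H2-Ab1 (3.20), Cd74 (3.03) and H2-Aa (2.93) also passed, but a single cell held 93.9% of the B cell list's UMIs in this cluster in KI replicate 1 and a single cell 97.7% in KI replicate 2. WT replicate 1 had such a cell too, with 95.6%, and WT replicate 2 had none. The count was 16 without KI replicate 1, 9 without KI replicate 2, 34 without WT replicate 1, 77 without WT replicate 2 and 12 with the DESeq2 Wald test.

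In cluster 3, 44 genes changed, 24 upward and 20 downward. Cd40lg rose from 6.82 ± 0.0563 to 46.1 ± 5.27 CPM (SD, n = 2; log2 change 2.75, adjusted p = 6.89e-06), with Zbtb16 (1.80), Anxa1 (1.69), Ly6a (1.53), S100a4 (1.35), Chn2 (1.40) and Tmem176b (1.30). S1pr5 (-2.05), Cd8a (-2.10), Lilr4b (-2.12), Pik3ap1 (-1.84), Ppm1a (-1.69), Rln3 (-1.62), Fam169b (-1.58), Racgap1 (-1.45) and Eomes (-0.98) fell. The count was 101 without WT replicate 1, 74 without WT replicate 2 and 6 with the DESeq2 Wald test.

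In cluster 5, 22 genes changed. Ly6c1 rose from 5.79 ± 1.91 to 52.2 ± 5.18 CPM (SD, n = 2; log2 change 3.26, adjusted p = 0.000500), Ccr2 by 3.16, Cd40lg by 3.14, Ckb by 2.69, Klra1 by 2.43 and Klrk1 by 2.18. Cbfa2t3 and Wfikkn2 were at 0 CPM in both WT libraries and at 15.9 CPM each in KI. Nr4a1 (-1.003), the kinase gene Pim2 (-0.88) and Rab3ip (-1.02) fell. The count was 3 without KI replicate 1, 0 without KI replicate 2, 105 without WT replicate 1, 187 without WT replicate 2 and 11 with the DESeq2 Wald test.

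The enlarged clusters themselves showed few differences. In cluster 4 the intermediate filament gene Vim fell from 470 ± 50.6 to 264 ± 15.4 CPM (SD, n = 2, log2 change -0.82, SE 0.14, adjusted p = 0.0105). It was the single gene outside the receptor and immunoglobulin loci to change. Outside these loci 406 genes had an unadjusted p under 0.05, among 7805 tested genes of any kind. Adam19 (-1.64), Rsrp1 (0.70) and S100a6 (-0.50) had the next smallest p-values and did not pass (adjusted p = 0.116 each). In cluster 6, 0 genes outside these loci changed by edgeR and 0 by DESeq2, among 5619 tested genes of any kind. An unadjusted p under 0.05 was found for 260 and 31 of them. Outside these loci Pim2 (-1.48, adjusted p = 0.238), Serpina3g (-0.84, adjusted p = 0.261) and Ly6c1 (1.40, adjusted p = 0.392) had the smallest p-values by edgeR. Counted apart, 2 receptor or immunoglobulin segment genes fell in cluster 4 and 1 in cluster 6, by edgeR and also by DESeq2. In cluster 4 Zbtb16, Id2 and Cd40lg, chosen after their values were seen, had log2 changes of -0.11, -0.05 and 0.34 and did not pass. WT replicates 1 and 2 had 79 and 138 cells in both clusters together, and in simulated data of cluster 4 the test recovered 32.6% of genes changed 2-fold and 88.3% of those changed 4-fold. The count in cluster 4 was 19 without WT replicate 1, 51 without WT replicate 2 and 2 without KI replicate 1, and that in cluster 6 was 11 without WT replicate 1, 9 without KI replicate 1 and 1 without WT replicate 2 or KI replicate 2.

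In cluster 9, 36 genes changed. The chemokine gene Cxcl10 rose from 66.6 ± 18.0 to 337 ± 234 CPM (SD, n = 2; log2 change 2.48, adjusted p = 2.87e-19), Icos by 2.62, Klrc2 by 2.86, Chn2 by 2.28, Id2 by 2.01, S100a4 by 2.00, Fcer1g by 1.95 and Rora by 1.93. The KI libraries differed for Cxcl10, at 503 CPM in replicate 1 and 171 CPM in replicate 2. Its p-value rests largely on the spread that the edgeR model shares over genes. Cd79b was at 47.2 CPM in WT and at 0 CPM in both KI libraries. Ccr9 (-1.60), Cd8b1 (-1.10), Ift80 (-1.40), Pkp3 (-1.32), Pik3ip1 (-1.26), Actn1 (-1.17) and Smc4 (-1.01) fell. The count was 18 without WT replicate 1, 22 without WT replicate 2, 55 without KI replicate 1 and 2 with the DESeq2 Wald test.

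In the low-UMI clusters 7 and 8, 3 and 27 genes changed. Klrk1 (2.16), Fcer1g (1.42) and AY036118 (1.00) rose in cluster 7. In cluster 8, whose cells had the highest median of mitochondrial UMIs (7.66%), Zbtb16 rose from 51.1 ± 4.88 to 728 ± 180 CPM (SD, n = 2; log2 change 3.77, adjusted p = 3.26e-05), with Atp8a2 (4.92), Lmo4 (4.25), Il2ra (4.02), Cd40lg (3.72), Tnfrsf25 (3.45) and Chn2 (3.32), and Ckb went from 0 CPM in both WT libraries to 203 CPM. Arl5c (-2.48), Ctla2a (-2.33), Myb (-2.06), Il6st (-1.81), Actn1 (-1.71), Itgae (-1.64) and Ift80 (-1.56) fell in cluster 8. Zbtb16, Lmo4, Cd40lg, Tnfrsf25 and Chn2 were also leading genes of cluster 4, and Ckb and Atp8a2 of cluster 6. Myb was a leading gene of cluster 2 and Itgae of cluster 0. Cluster 8 had no cell type name, so a different mixture of cells in it cannot be told apart from a change within cells of a kind. The count in cluster 7 was 30 without WT replicate 2, 6 without KI replicate 2 and 0 with the DESeq2 Wald test, and that in cluster 8 was 92 without WT replicate 1, 6 without KI replicate 1, 15 without KI replicate 2 and 3 with the DESeq2 Wald test.

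Effects of the genotype were compared directly between cluster 0 and each other tested cluster. The effect differed for 611 pairs of gene and cluster. Dapl1 had a log2 change of 0.80 in cluster 0 and -0.32 in cluster 1 (adjusted p = 2.20e-10 for the difference), Cd8b1 of -0.28 and 0.89, Ly6c1 of -0.63 and 2.25, and Klrd1 of 1.05 and 0.32. Genes of ribosomal proteins were 72 of the 142 that differed between clusters 0 and 1, with medians of 0.32 in cluster 0 and 0.02 in cluster 1. Left-out libraries gave totals of 391, 365 and 406 without WT replicate 1, WT replicate 2 and KI replicate 1.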

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

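The results here were singled out because the effect of genotype differed between groups of cells in a planned test, and the sorting of these genes into ribosomal protein genes and others was chosen only after the result was seen. Relative to cluster 0 (Cd8b1, Ccr9, Dapl1), the KI effect differed for 142 genes in cluster 1 (Ccl5, Ly6c2), 161 in cluster 2 (Nr4a1, Egr1), 163 in cluster 3 (Fcer1g, Ncr1), 87 in cluster 4 (Zbtb16, Il4), 9 in cluster 5 (Prdm16, Cd7), 19 in cluster 6 (Ckb, Cxcr6), 5 in cluster 7, 18 in cluster 8 and 7 in cluster 9 (Ifit3, Isg15). Genes of ribosomal proteins were 72, 70, 76, 53 and 4 of those in clusters 1, 2, 3, 4 and 6, and 0 in clusters 5, 7, 8 and 9. Those that differed from cluster 1 had a median log2 change of 0.32 in cluster 0 and of 0.02 in cluster 1, and those that differed from cluster 3 had 0.32 and -0.05. Nr4a1 changed by -0.67 in cluster 0 and 0.80 in cluster 2, Egr1 by -0.64 and 0.75, and Klrd1 by 1.05 and -0.19. The total of 611 was 391 without WT replicate 1, 365 without WT replicate 2, 406 without KI replicate 1 and 475 without KI replicate 2. No technical explanation of these differences was tested.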

How the results depend on the processing

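Among the alternatives in this section, those chosen only after the data were seen were the tests without low-UMI clusters and without cluster 3, the limma test on cells as they fall and the stricter cell filters for cluster shares. Leaving out a library leaves a group with 1 library, which is assumed to vary like the other group. No cluster got the name of another cell type, so no cluster was left out on that ground. Cluster 3, in which 4 natural killer cell markers tied with 4 type 1 cytotoxic markers, was left out in an added test: 491 genes then changed over all cells, 8 gene lists passed, and the natural killer cell list had adjusted p = 5.62e-07. WT replicates 1 and 2 had 79 and 138 cells in clusters 4 and 6 together, which limits what the tests within these clusters can find. The cause was not tested for the changes below, except where fewer genes, cells or libraries enter by construction.

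Shares of clusters 4 and 6 kept their direction in all alternatives run. The number of clusters with changed shares was 7, and 4 with cells thinned, 4 with receptor genes kept in the clustering, 8 without low-UMI clusters and 0 to 3 with a library left out. The share of cluster 7, which did not pass, had a log2 change of -0.11, and of 0.19 with TMM over clusters, 0.72 with genes centred within libraries, 0.72 at resolution 0.3, 1.35 with stricter filters and -0.30 to 0.054 with a library left out. Other shares that changed sign did not pass in the main test: cluster 1 with centred genes (0.42), cluster 5 with thinned cells (-0.10) and cluster 12 with a library left out (-0.0096 to 1.09). The number of γ V genes with changed use was 4, and 0 to 4 with a library left out, and Tcrg-V7 went from 0.23 to -0.031 by most UMIs and to -0.24 to 0.63 with a library left out. Of the gene lists, 8 passed camera, 0 with an estimated correlation and 2 by fry.

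Over all cells 435 genes changed, 895 without a filter on low counts, 408 without low-UMI clusters and 75 to 755 with a library left out. With the same mixture of clusters in every library 10 genes passed, against 383 in the limma test on cells as they fall. Of the 435 genes 388 kept their direction. Among named genes and list members, these changed sign: Asb2 -0.31, Ccr6 0.19, Cd79b 0.15, Cxcr3 -0.039, Dapl1 0.23, Egr1 0.43, Egr2 0.46, Entpd1 -0.076, Fasl -0.14, Ifit3 0.043, Igfbp4 -0.041, Il1r1 0.013, Nr4a1 0.45 and, for Gata3, all cells summed, -0.0226.

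Within clusters the total was 248. With the DESeq2 Wald test it was 102, with 12 in cluster 2, 6 in cluster 3, 11 in cluster 5, 0 in cluster 7, 3 in cluster 8 and 2 in cluster 9. With cells thinned it was 119, with 8 in cluster 2, 24 in cluster 3, 0 in cluster 4, 12 in cluster 5, 0 in cluster 7, 4 in cluster 8 and 1 in cluster 9. Without a filter on low counts it was 565, with 134 in cluster 0, 77 in cluster 1, 97 in cluster 2, 73 in cluster 3, 12 in cluster 4, 89 in cluster 5, 7 in cluster 6 and 8 in cluster 7. With doublets kept, cluster 1 had 20, cluster 2 had 28, cluster 4 had 3, cluster 8 had 12 and cluster 9 had 16. With stricter cell filters, cluster 2 had 33, cluster 6 had 2, cluster 7 had 1, cluster 8 had 0 and cluster 9 had 18. With receptor genes removed, cluster 7 had 1. With a library left out the total was 133 to 626, with 0 to 113 in cluster 0, 3 to 155 in cluster 1, 9 to 77 in cluster 2, 35 to 101 in cluster 3, 1 to 51 in cluster 4, 0 to 187 in cluster 5, 1 to 11 in cluster 6, 3 to 30 in cluster 7, 6 to 92 in cluster 8 and 18 to 55 in cluster 9. Differences between clusters numbered 611, and 365 to 475 with a library left out.

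With the replicate number as a replicate block, 1310 genes changed over all cells and 679 within clusters, with 236 in cluster 0, 118 in cluster 1, 89 in cluster 3, 5 in cluster 4, 106 in cluster 5, 6 in cluster 7 and 9 in cluster 8. The labels give these libraries a shared number and no shared origin, and the deviations of WT replicate 1 and KI replicate 1 from their group means had r = 0.313 over 5635 genes.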

Other observations

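The tests on depth (for cluster shares and for genes over all cells), on WT cells or RNA in KI libraries, on cells using Trdv2-2 in place of Vδ6 and the V gene values in the next paragraph were chosen only after the results were seen.

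In WT, V gene use in clusters 4 and 6 differed from that in other clusters. A Vδ6 UMI was found in 74.7% (59 of 79) and 73.2% (101 of 138) of these cells in WT replicates 1 and 2, against 30.2% and 30.6% of WT cells in other clusters, and a Tcrg-V1 UMI in 75.9% and 76.8%, against 34.4% and 37.6% in clusters other than 3, 4, 6 and 10. Trav13-4-dv7 was found in 3.80% and 5.80% of them, against 20.7% and 25.7% elsewhere. Of the Vδ6 copies, Trav15d-1-dv6d-1 was found in 45.6% and 55.8% of these WT cells, against 4.76% and 5.76% elsewhere. KI cells of clusters 4 and 6 had it in 0.417% and 1.39%. Trav15-1-dv6-1 was found in 41.8% and 21.7% of these WT cells and in 62.5% and 65.6% of these KI cells. Similar family totals in the 2 groups therefore do not mean the same copy. In KI, Tcrg-V1 was found in 78.2% and 81.3% of the cells of clusters 4 and 6, against 40.0% and 37.2% in clusters other than 3, 4, 6 and 10, and Vδ6 in 67.3% and 68.3%, against 68.0% and 73.2% elsewhere. Tcrg-V6 was found in 23.6% and 40.0% of the cells of cluster 10 (Blk, Cd163l1) in WT (39 of 165 and 48 of 120) and in 0 of 12 and 0 of 14 in KI (upper exact 95% limits 26.5% and 23.2%). In cluster 3 (Fcer1g, Ncr1) it was found in 0.495% and 1.74% of WT and 14.7% and 10.4% of KI cells.

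The larger share of clusters 4 and 6 (Zbtb16, Il4, Cd40lg) in KI was weighed against 3 technical explanations. A difference in UMIs per cell was argued against by thinning, after which the lower of the log2 changes of these clusters was 3.17. Loss of cells to the filters was argued against by a bound: with every removed WT barcode counted as a cell of these clusters, the lowest KI share was still 1.66 times the highest WT share. Cells of the αβ lineage in the sort were argued against by Trdc, found in KI cells of these clusters 0.954 times as often as in other KI cells after thinning (0.963 in the other library). The genotype may therefore be the source, as a hypothesis that was not tested.

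The changes over all cells, such as those of Zbtb16, Cd40lg and Blk, were weighed against the mixture of clusters and depth. WT cluster profiles mixed in KI shares gave a median of 0.660 of the observed log2 change over the 435 genes (0.723 for those that rose and 0.551 for those that fell), with the same direction in 426, so a shift in the mixture may account for most of it. Thinning left a median ratio of 1.02, but sums scaled to library size hardly move with thinning, so depth stays open. Cells that switch such genes on are placed in clusters by these genes, so a shift in mixture and a change of regulation stay open, as does the genotype as an untested biological explanation.

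Trdv2-2 transcripts in KI, 14.7% of the δ V gene UMIs, were weighed against 3 explanations. WT cells or their RNA were argued against by Trav13-4-dv7, whose ratio to Trdv2-2 in KI was at most 0.00837 of that in WT. Cells with Trdv2-2 in place of Vδ6 were argued against by the share of KI cells with a Trdv2-2 UMI, which was at most 0.992 times as high without a Vδ6 UMI as with it, while in WT it was 1.84 and 1.56 times as high. KI cells with a Trdv2-2 UMI held at most 0.585 times the UMIs of it that such WT cells held, which met the prediction written beforehand. A comparison with Vδ6 was not part of that prediction. KI cells with a Vδ6 UMI also held fewer UMIs of it than such WT cells (0.603 to 0.692 times). Over all cells Vδ6 UMIs were more abundant in KI, 519 against 389 CPM. Fewer transcripts per cell than from a rearranged gene therefore cannot be told apart from a lower yield of δ V transcripts in the cells that have them. Whether KI mice carried 1 or 2 copies of the allele is not in the labels, so a second, unaltered copy of the locus stays open. Reads shared between V gene copies were not tested, and neither were sequencing runs: the labels give several read configurations without saying which library had which, and read length bears on V gene counts.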
